A study of Mus musculus with 16 samples.

How the data were processed

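Liver RNA from 16 male mice was hybridised as biotinylated cRNA, made from 1 µg of total RNA per mouse, to Illumina mouse BeadChips with 1 array per mouse. Wild type and SHP knockout mice were on chow or on a western diet for 6 months from the age of 4 months, with 4 mice per group, and livers were taken at 10 months after an overnight fast. The deposited non-normalized table gives, per the file headers, a signal intensity per probe and array, exported by the authors from BeadStudio (version not stated). Its lowest values lie well above 0 and the array means differ, so it is neither background-subtracted nor scaled. Beside each signal the deposited table holds, per the file headers, a detection p-value (p_value) that the authors exported from BeadStudio, computed against the negative control beads of the same array. The series values of the authors are a linear intensity that holds negative values and has nearly equal quantiles in every array, so they are background-subtracted and quantile-normalized as far as the values show, with settings not stated. Each array of the series values was checked against the non-normalized table: Spearman's rho was at least 0.999993 for the same array and at most 0.913 for any other.

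The non-normalized signal of 25697 probes was background-corrected and quantile-normalized on the log2 scale with neqc of limma 3.58.1 (R 4.3.3), which infers the negative controls from the detection p, with an offset of 16. Probes with a detection p below 0.05 in at least 4 of the 16 arrays were kept (13196). Probes were named by the platform annotation, which gave 1 symbol for 23978 probes and none for 1719, with no probe given several. Of the named probes 23962 matched the mouse gene table of assembly GRCm38.p6 by Entrez ID, and 0 symbols changed. That assembly was used for names and gene order alone. Of the probes kept, 12421 were named and 775 were not and were left out. For each gene the probe with the highest mean was used, which gave 9095 genes, 2386 of them with several probes. Another detected probe of the same gene pointed the opposite way in 0, 2, 13, 1 and 0 of the 16, 520, 771, 207 and 176 called genes with such a probe, in the order of the comparisons below. Probes of close paralogs, such as Gsta1 and Gsta2, Cyp4a14 and Cyp4a31 or the Serpina1 family, can bind each other's transcripts. A gene is called at background in a group when all its probes miss a detection p of 0.05 in all 4 arrays. Its fold is then a lower bound.

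One linear model with a mean per group was fitted to all 16 arrays with limma (lmFit, then eBayes with an intensity trend), which leaves 12 residual degrees of freedom. The comparisons were knockout against wild type on chow and on western diet, western diet against chow in wild type and in knockout, and the diet by genotype interaction, the diet effect in knockout minus that in wild type. Tests were two-sided, a gene passed at a Benjamini-Hochberg adjusted p below 0.05, and adjusted p values of genes are from limma. The number of arrays limits the precision. The 30 gene lists, of pathways and of markers of the cell types a liver sample can hold, were fixed before the data were examined, as were the comparisons, the tests and the rule for named genes. Some genes stand in more than 1 list. Lists with at least 3 members were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. Beside it stand camera with an estimated correlation and fry, and counts of members that passed over all genes and adjusted over the list alone. Named genes were 17 key genes, the 8 largest changes each way among genes that passed and whose 2 groups did not overlap, the 4 members with the largest changes in a called list and 2 in other lists, and the 10 interaction genes with the smallest p. The fit and the list test were tested on simulated arrays, drawn from each gene's mean and fitted spread, with known changes added. Single scores were compared by an exact permutation test in R, and plots were drawn with matplotlib 3.10.9 on Python 3.11.15.

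The alternatives were quantile normalization without background correction, a normexp correction without negative controls (offset 50), called the background alternatives, median scaling in place of quantile, the authors' processed values, no detection filter, and a strict filter (detection p below 0.01 in all 4 arrays of at least 1 group). Further ones were the mean of a gene's detected probes, every probe as its own feature, the 8 arrays compared alone, a robust variance prior, array weights, the replicate number as a block, and leaving out each array in turn, which was extended to the lists and to arrays outside a comparison after seeing the data. Of the measured data no column was left out. The slides that held the arrays are not given, so slide was not a term in any model.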

Results

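Liver RNA of 16 male mice aged 10 months was measured on Illumina BeadChips, 1 array per mouse, in 4 groups of 4. Wild type and SHP knockout mice were each on chow or on a western diet for 6 months. SHP, encoded by Nr0b2, is a nuclear receptor without a DNA-binding domain that represses bile acid synthesis genes. Livers were taken after an overnight fast. The raw signal averaged 319 ± 40.1 in wild type on chow, 294 ± 25.8 in knockout on chow, 361 ± 16.5 in wild type on western diet and 316 ± 32.7 in knockout on western diet (SD, n = 4). Of 25697 probes, 45.1% ± 1.25 in wild type on chow, 45.4% ± 0.969 in knockout on chow, 49.5% ± 1.05 in wild type on western diet and 46.0% ± 0.929 in knockout on western diet were detected (SD, n = 4).

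The single Nr0b2 probe was at background in every array: it was detected in 0 of the 16, and its lowest detection p was 0.227. Per group the raw signal spanned 47.8 to 51.4 in wild type and 53.2 to 59.7 in knockout on chow, and 49 to 55.2 in wild type and 47.1 to 55.6 in knockout on western diet. The probe therefore checked neither the loss of the gene nor the genotype labels, and no change of Nr0b2 is given. Of the 17 key genes 12 were tested, 3 had no probe named in the annotation used, and Nr0b2 and Cd36 were detected in 0 arrays. Fasn was detected in 8 of 16, which limits what its null results show. Values below are log2 differences ± SE with n = 4 mice per group.

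On chow, the comparison of knockout with wild type asked what loss of SHP changes in the liver without a dietary load. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 6.27-fold higher in knockout livers (2.65 ± 0.39, adjusted p = 0.000557), with a level of 10.39 ± 0.76 against 7.74 ± 0.47 in wild type (log2 mean ± SD, n = 4), and 1 of 16 measured bile acid synthesis genes rose and 0 fell (1 and 0 adjusted over the list alone, camera adjusted p = 0.404). The largest rise was in Asns, asparagine synthetase, at 10.3-fold (3.37 ± 0.36), followed by Hr, a nuclear receptor corepressor, at 9.60-fold (3.26 ± 0.22). Extl1, a glycosyltransferase of the exostosin family, rose 7.41-fold (2.89 ± 0.33) and Cav1, the caveolae coat protein, 5.29-fold (2.40 ± 0.20). The strongest falls were in Serpina12, the adipokine vaspin (8.28-fold, -3.05 ± 0.30), and Slc39a4, a zinc importer (6.68-fold, -2.74 ± 0.21), and Pparg, a nuclear receptor that drives lipid storage, fell 3.60-fold (-1.85 ± 0.19, adjusted p = 5.91e-06).

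Further rises came from Csad, an enzyme of taurine synthesis (1.93 ± 0.13), Gldn (at least 2.56-fold, 1.77 ± 0.22), whose wild type level was at background, and Dct, dopachrome tautomerase (1.75 ± 0.27). Further falls came from Xkr8, a phospholipid scramblase at background in the knockout (at least 3.83-fold lower, -2.21 ± 0.16), Serinc2 (-1.90 ± 0.21), Olig1 (-1.89 ± 0.23), Treh, which encodes trehalase (-1.68 ± 0.23), and Bsdc1 (-1.63 ± 0.14). In all of these genes the 4 knockout values lay outside the 4 wild type values, which the rule for naming them required. The highest adjusted p of these was 0.00129, for Dct. Among transporters, the sterol exporter subunit Abcg5 (0.61 ± 0.12, adjusted p = 0.0189) and the lipoprotein receptor Scarb1 (0.93 ± 0.17, adjusted p = 0.00750) rose, while the organic anion carrier Slco1a4 (-0.91 ± 0.15, adjusted p = 0.00265) fell. Chac1, which degrades glutathione, fell (-1.14 ± 0.23, adjusted p = 0.0189). Cyp8b1 (0.28 ± 0.24, adjusted p = 0.740), Abcb11 (0.31 ± 0.15, adjusted p = 0.486), Srebf1 (0.15 ± 0.29), Fasn (0.29 ± 0.18), Scd1 (-0.14 ± 0.14), Cidec (-0.59 ± 0.35), Pck1 (0.25 ± 0.23), Fgf21 (-0.76 ± 0.34), Col1a1 (-0.13 ± 0.19) and Cyp2b10 (-1.94 ± 0.46, adjusted p = 0.0554) did not pass. In other settings Cyp2b10 passed under both background alternatives and with median scaling and without wild type western replicate 1 or 2 or knockout western replicate 1, 2, 3 or 4 (lowest adjusted p = 0.0166).

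Cholesterol synthesis genes were shifted up as a list on chow: 2 of 18 members rose (12 adjusted over the list alone, camera adjusted p = 1.90e-08, 0.487 with an estimated correlation). The passing members were Sqle (1.45 ± 0.26, adjusted p = 0.00638), squalene epoxidase, and Dhcr7 (0.83 ± 0.19, adjusted p = 0.0438), the reductase of 7-dehydrocholesterol. In methionine and one-carbon metabolism, 1 of 17 members rose (4 adjusted over the list alone, camera adjusted p = 0.0135, 0.487 with an estimated correlation), and Csad was the passing member. The list's median was 0.094 and turned to -0.025 with median scaling. Lymphocyte and NK cell markers were shifted down as a list (median -0.29) although 0 of 10 members passed (0 adjusted over the list alone, camera adjusted p = 0.0159, 0.839 with an estimated correlation). In limma 2 members had an unadjusted p below 0.05. The lists were refitted without each of the 16 arrays in turn, those outside the comparison included since the fit pools their spread, which was chosen after seeing the data. Lymphocyte and NK cell markers were not called without wild type chow replicate 3 (adjusted p = 0.441) or without knockout chow replicate 1 (adjusted p = 0.0511) or with the authors' values (adjusted p = 0.140). Their median was -0.13 without wild type chow replicate 3 and -0.49 without wild type chow replicate 1. The 2 cholesterol synthesis genes that rose became 1 without wild type chow replicate 1, 3 or 4, knockout chow replicate 1, 3 or 4, wild type western replicate 1 or 4 or knockout western replicate 2, 6 without knockout western replicate 3, 1 with median scaling and 0 with the authors' values. Methionine and one-carbon genes were not called without wild type chow replicate 4 (adjusted p = 0.0693) or without knockout chow replicate 3 (adjusted p = 0.0554). The 1 methionine and one-carbon gene that rose became 2 without knockout chow replicate 2 or wild type western replicate 2.

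Of 9095 genes, 76 passed, 40 up and 36 down (21 up and 39 down when arrays were scaled by their medians), 19 and 18 of them by more than 2-fold. At an unadjusted p below 0.05 there were 972, and in 593 genes the groups did not overlap, where chance gives 2.86%. Of the 100 measured genes nearest to Nr0b2 on its chromosome, 12 passed, a share of 12% against 0.712% of the other 8995 genes (Fisher's exact test, p = 2.76e-11), and without these 100 genes 59 passed. The 12 included Extl1, Serinc2, Xkr8 and Bsdc1. The count was 124 with array weights and 49 without wild type chow replicate 3. On leaving out 1 array some calls were lost in at least 1 of 16 fits. Dhcr7 (10 fits, adjusted p = 0.128) was weakest without wild type chow replicate 4. Chac1 (6 fits, adjusted p = 0.0866) was weakest without knockout chow replicate 4. Abcg5 (4 fits, adjusted p = 0.0834) was weakest without wild type chow replicate 3. Sqle (adjusted p = 0.0719) was lost with the authors' values. Abcg5 (adjusted p = 0.270) was lost with median scaling. Dhcr7 (adjusted p up to 0.0939) was lost with median scaling, with the authors' values and without a detection filter.

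On western diet, the same comparison asked how loss of SHP alters the liver under a long dietary load. Gpnmb, a marker of lipid-laden macrophages, was 21.1-fold lower in knockout (-4.40 ± 0.37), Cidea and Cidec, coat proteins that enlarge lipid droplets, 21.4-fold (-4.42 ± 0.61) and 10.2-fold lower (-3.35 ± 0.35), and Col1a1, the main fibrillar collagen chain, 3.18-fold lower (-1.67 ± 0.19). Hsd3b5, a steroid reductase expressed in male liver, was 55.3-fold higher (5.79 ± 0.48) and was detected in 1 of the 4 wild type arrays. The bile acid enzymes Cyp7a1, Cyp8b1 (12-alpha-hydroxylation) and Cyp7b1 (oxysterol 7-alpha-hydroxylation) were 3.08-fold (1.62 ± 0.39), 2.68-fold (1.42 ± 0.24) and 4.89-fold (2.29 ± 0.28) higher, and the highest adjusted p of these was 0.00533, for Cyp7a1. In all, 6 of 16 measured bile acid synthesis genes rose and 1 fell (6 and 2 adjusted over the list alone, camera adjusted p = 0.133).

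**Figure D1:**
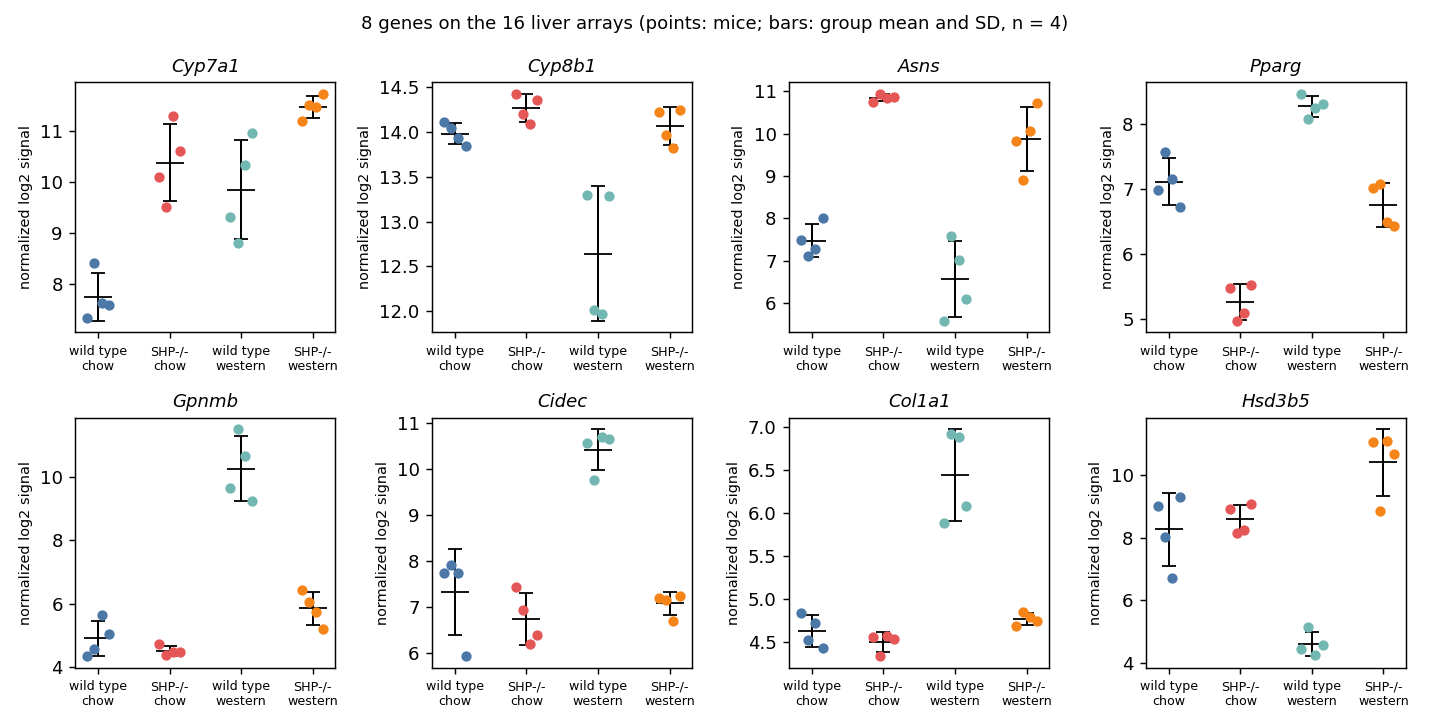
Log2 signal of 8 genes in each of the 4 groups, with 1 point per mouse and bars for the mean ± SD (n = 4). Gpnmb, Cidec and Col1a1 were high in wild type on western diet and lower in the other groups, whereas Hsd3b5 was lowest in wild type on western diet.

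Macrophage and Kupffer cell markers fell as a list: 19 of 22 members fell (19 adjusted over the list alone, camera adjusted p = 3.36e-19, 0.0680 with an estimated correlation). Examples besides Gpnmb were Mmp12 (-2.97 ± 0.27), Trem2 (-2.56 ± 0.32) and Lgals3 (-2.49 ± 0.24). Of inflammatory cytokines and signalling genes, 17 of 21 measured fell (18 adjusted over the list alone, camera adjusted p = 1.60e-13, 0.0680 with an estimated correlation). They included the chemokines Ccl4 (-2.33 ± 0.36) and Cxcl1 (-1.63 ± 0.27), the receptor Tlr2 (-1.83 ± 0.16) and Tnfaip3 (-1.48 ± 0.19), an inhibitor of NF-kappaB signalling. Of fibrosis and stellate cell markers, 18 of 24 measured fell (19 adjusted over the list alone, camera adjusted p = 2.04e-13, 0.0984 with an estimated correlation). These included Col3a1 (-1.65 ± 0.18), Timp1 (-1.68 ± 0.26) and Mmp13 (-1.67 ± 0.39). In lipid droplet and PPARgamma targets, 6 of 16 members fell (9 adjusted over the list alone, camera adjusted p = 0.00225, 0.196 with an estimated correlation). Lpl (-2.57 ± 0.34) and Plin4 (-1.5 ± 0.38) fell beside Cidea and Cidec. Proliferation genes fell as well: 5 of 15 members fell (5 adjusted over the list alone, camera adjusted p = 0.0121, 0.365 with an estimated correlation). These were the replication helicase subunits Mcm5 (-0.63 ± 0.18) and Mcm6 (-0.75 ± 0.21), the mitotic kinase Cdk1 (-0.61 ± 0.15) and Top2a (at least 1.19-fold lower, -0.50 ± 0.13) among others. Without knockout western replicate 3 the change was -0.88 for Plin4. Proliferation genes were not called without wild type western replicate 2 (adjusted p = 0.0717) or without knockout western replicate 1 (adjusted p = 0.0816). The 5 proliferation genes that fell became 3 without wild type western replicate 2 and 2 with the authors' values.

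Male-biased liver genes were higher in knockout livers: 14 of 18 members rose (14 adjusted over the list alone, camera adjusted p = 1.37e-10, 0.0984 with an estimated correlation). Beside Hsd3b5 and Cyp7b1 these included Serpina1e (2.58 ± 0.49) and Susd4 (2.51 ± 0.25). Cholesterol synthesis genes rose again: 9 of 18 members rose (12 adjusted over the list alone, camera adjusted p = 6.92e-06, 0.315 with an estimated correlation). The largest changes were in Fdps (1.11 ± 0.38), Msmo1 (1.00 ± 0.29), Stard4 (0.94 ± 0.30) and Tm7sf2 (0.94 ± 0.17). The 9 cholesterol synthesis genes that rose became 4 without wild type western replicate 2, 5 without knockout western replicate 3 and 3 with median scaling. Without knockout western replicate 3 the change was 0.52 for Fdps, 0.60 for Msmo1 and 0.49 for Stard4. Their median of 0.59 was 0.37 without knockout western replicate 3 (camera adjusted p = 0.000278). In methionine and one-carbon metabolism, 9 of 17 members rose and 1 fell (10 up and 1 down adjusted over the list alone, camera adjusted p = 6.11e-05, 0.0680 with an estimated correlation). Csad (2.03 ± 0.13), Dmgdh, which demethylates dimethylglycine (1.41 ± 0.18), and Cth, the last enzyme of cysteine synthesis from methionine (1.04 ± 0.25), rose, and Psat1, an enzyme of serine synthesis, fell (-1.36 ± 0.16).

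Other large rises were in Dct (3.38 ± 0.27), Asns (3.30 ± 0.36), Cav1 (2.67 ± 0.20), Obp2a (2.63 ± 0.32) and Extl1 (2.16 ± 0.33). Other large falls were in the glutathione transferase Gsta1 (-3.68 ± 0.36), Ly6d (-3.47 ± 0.29), Serpina12 (-3.16 ± 0.30) and Sdcbp2, which was at background in the knockout (at least 9.17-fold lower, -3.45 ± 0.15). In these genes the 4 knockout values lay outside the 4 wild type values, which the rule for naming them required. Of the remaining key genes, Pck1, the gluconeogenic carboxykinase, rose (1.25 ± 0.23, adjusted p = 0.000593), as did the bile salt export pump Abcb11 (0.48 ± 0.15, adjusted p = 0.0300). Pparg (-1.52 ± 0.19, adjusted p = 1.31e-05), the fasting hormone Fgf21 (-1.39 ± 0.34, adjusted p = 0.00664) and the desaturase Scd1 (-0.42 ± 0.14, adjusted p = 0.0393) fell. Srebf1 (-0.18 ± 0.29, adjusted p = 0.716), Fasn (0.21 ± 0.18, adjusted p = 0.471) and Cyp2b10 (-0.53 ± 0.46, adjusted p = 0.472) did not pass.

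In all, 1799 of 9095 genes passed, 802 up and 997 down. With median scaling, which lowered the median of all genes to -0.16, the split was 208 up and 1691 down. More than 2-fold changes numbered 64 up and 255 down, the unadjusted p was below 0.05 in 2910, and the groups did not overlap in 1925 (chance share 2.86%). Of the 100 measured genes nearest to Nr0b2, 41 passed (41% against 19.5%), and 1749 passed without them. Not all of this need reflect the locus, since the macrophage genes C1qa, C1qb and C1qc there fell (-0.90 to -1.42). On leaving out 1 array some calls were lost in at least 1 of 16 fits. Scd1 (6 fits, adjusted p = 0.111) was weakest without knockout western replicate 1. Fdps (13 fits, adjusted p = 0.112), Stard4 (2 fits, adjusted p = 0.0951), Mcm5 (1 fit, adjusted p = 0.0703) and Mcm6 (2 fits, adjusted p = 0.0666) were weakest without wild type western replicate 2. Abcb11 (4 fits, adjusted p = 0.105) was weakest without knockout western replicate 2. Msmo1 (2 fits, adjusted p = 0.0527) was weakest without knockout western replicate 3. Cdk1 (adjusted p = 0.119) and Top2a (adjusted p = 0.110) were lost with the authors' values. Abcb11 (adjusted p = 0.162), Msmo1 (adjusted p = 0.0716) and Stard4 (adjusted p = 0.105) were lost with median scaling. Scd1 (adjusted p up to 0.163) was lost with median scaling and without a detection filter. Fdps (adjusted p up to 0.0817) was lost under both background alternatives, with median scaling, with the authors' values and without a detection filter.

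**Figure D2:**
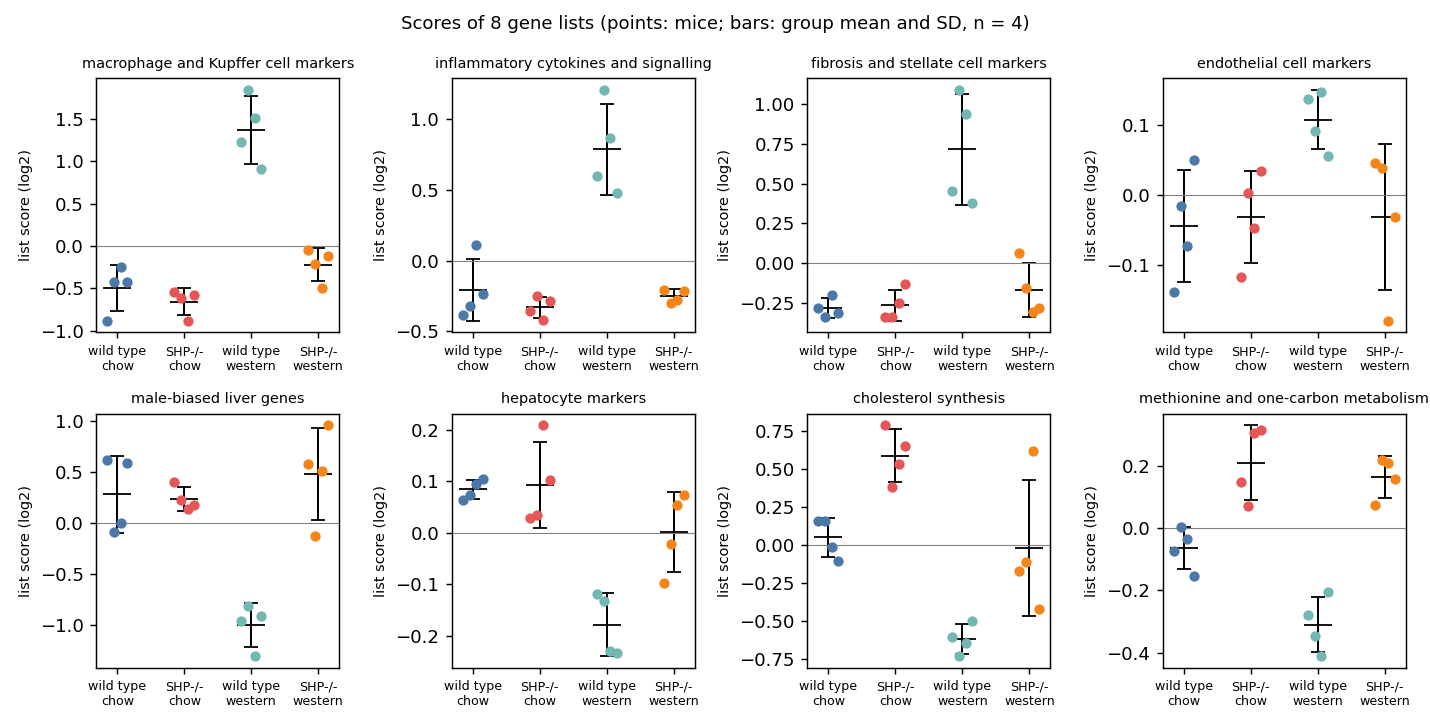
Mean score of 8 gene lists per array, as the log2 deviation from the mean of all 16 arrays averaged over the list's members, with 1 point per mouse and bars for the mean ± SD (n = 4). The macrophage score was 1.37 ± 0.40 in wild type on western diet and -0.22 ± 0.20 in knockout on the same diet.

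In wild type mice, the comparison of western diet with chow asked what 6 months of the diet change in the liver. The macrophage gene Gpnmb rose 40.9-fold (5.35 ± 0.37) from 4.90 ± 0.57 to 10.26 ± 1.02 (log2 mean ± SD, n = 4), and was detected in 2 of the 4 arrays on chow. The lipid droplet genes Cidea and Cidec rose 26.3-fold (4.72 ± 0.61) and 8.56-fold (3.10 ± 0.35), and Col1a1 3.50-fold (1.81 ± 0.19). The desaturase Scd1 rose 3.96-fold (1.99 ± 0.14) and its transcription factor Srebf1 3.45-fold (1.79 ± 0.29). Cyp7a1 rose 4.35-fold (2.12 ± 0.39), whereas Cyp8b1 fell 2.53-fold (-1.34 ± 0.24), and 2 of 16 measured bile acid synthesis genes rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 0.738). The male-liver steroid reductase Hsd3b5 fell 12.6-fold (-3.65 ± 0.48), and the highest adjusted p of these was 0.000401, for Cyp7a1.

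Macrophage and Kupffer cell markers rose in nearly every member: 20 of 22 members rose (20 adjusted over the list alone, camera adjusted p = 3.46e-18, 0.191 with an estimated correlation). Examples were Mmp12 (3.48 ± 0.27), Lgals3 (2.99 ± 0.24) and Trem2 (2.92 ± 0.32). The mean score of the list rose by 1.87, and that of endothelial cell markers by 0.15. Of inflammatory cytokines and signalling genes, 17 of 21 measured rose (19 adjusted over the list alone, camera adjusted p = 5.33e-10, 0.191 with an estimated correlation). These included Ccl4 (2.34 ± 0.36), Tlr2 (1.68 ± 0.16), Cxcl1 (1.56 ± 0.27) and Cxcl10 (1.5 ± 0.23). Of fibrosis and stellate cell markers, 19 of 24 measured rose (19 adjusted over the list alone, camera adjusted p = 1.23e-11, 0.191 with an estimated correlation). Col3a1 (at least 4.54-fold, 2.46 ± 0.18) and Timp1 (at least 3.41-fold, 2.09 ± 0.26) rose from background, and Mmp13 (1.68 ± 0.39) rose too. Proliferation genes rose: 9 of 15 members rose (9 adjusted over the list alone, camera adjusted p = 0.000256, 0.191 with an estimated correlation). The largest rise was in Mcm6 (1.36 ± 0.21). Mcm2 (at least 1.52-fold, 0.89 ± 0.16), Cdk1 (at least 1.40-fold, 0.77 ± 0.15) and Nusap1 (at least 1.38-fold, 0.74 ± 0.13) rose from background.

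Among lipid lists, 7 of 16 measured lipid droplet and PPARgamma targets rose and 2 fell (8 up and 2 down adjusted over the list alone, camera adjusted p = 0.00468, 0.191 with an estimated correlation). Lpl (3.18 ± 0.34) and Vldlr (1.75 ± 0.32) also rose. Of fatty acid and triglyceride synthesis genes, 11 of 22 measured rose and 2 fell (11 up and 2 down adjusted over the list alone, camera adjusted p = 0.0131, 0.455 with an estimated correlation). Thrsp (2.62 ± 0.71) rose beside Scd1 and Srebf1, and Lpin1, a phosphatidate phosphatase, fell (-2.40 ± 0.52). Cholesterol synthesis genes fell: 7 of 18 members fell (8 adjusted over the list alone, camera adjusted p = 4.42e-05, 0.287 with an estimated correlation). The largest falls were in Tm7sf2 (-1.60 ± 0.17), Sqle (-1.55 ± 0.26), Cyp51 (-1.49 ± 0.23) and Stard4 (-1.16 ± 0.30). The 7 cholesterol synthesis genes that fell became 11 without knockout western replicate 3. The receptor Pparg rose (1.16 ± 0.19, adjusted p = 0.000121).

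Male-biased liver genes fell in wild type on western diet: 10 of 18 members fell (11 adjusted over the list alone, camera adjusted p = 8.21e-06, 0.191 with an estimated correlation). Beside Hsd3b5 these were led by Serpina1e (-3.53 ± 0.49), Susd4 (-3.09 ± 0.25) and Elovl3 (-2.49 ± 0.42). Hepatocyte markers fell by less: 7 of 18 members fell (7 adjusted over the list alone, camera adjusted p = 0.0250, 0.191 with an estimated correlation). These were the urea cycle enzymes Cps1 (-0.66 ± 0.15) and Ass1 (-0.49 ± 0.14), the histidine and tyrosine catabolic enzymes Hal (-0.90 ± 0.21) and Hpd (-0.88 ± 0.12), and 3 others. In methionine and one-carbon metabolism, 1 of 17 members rose and 6 fell (2 up and 8 down adjusted over the list alone, camera adjusted p = 0.0186, 0.191 with an estimated correlation). Cbs (-0.98 ± 0.15), Shmt1 (-0.68 ± 0.16) and Cth (-0.79 ± 0.25) fell and Psat1 rose from background (at least 2.10-fold, 1.34 ± 0.16). Of nuclear receptors and partners of the SHP pathway, 1 of 21 measured rose and 8 fell (2 up and 12 down adjusted over the list alone, camera adjusted p = 0.0343, 0.220 with an estimated correlation). Nr1i3 (-1.13 ± 0.19), Nr5a2 (-0.78 ± 0.12) and Cebpb (-0.79 ± 0.22) fell and Pparg rose. Genes of the SHP pathway were not called without wild type chow replicate 3 (adjusted p = 0.0620) or without wild type western replicate 2 (adjusted p = 0.0621) or without wild type western replicate 3 (adjusted p = 0.0578). The 8 genes of the SHP pathway that fell became 3 with median scaling. The 6 methionine and one-carbon genes that fell became 3 with median scaling.

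The other largest rises were in Ly6d (4.65 ± 0.29), Gsta1 (4.39 ± 0.36), S100a11 (3.76 ± 0.16) and Anxa2 (3.62 ± 0.18) and, from background, Sdcbp2 (at least 8.95-fold, 3.52 ± 0.15). The other largest falls were in the vasopressin receptor Avpr1a (-2.45 ± 0.24), Cyp7b1 (-2.40 ± 0.28) and Gadd45g (-2.20 ± 0.23). In the named genes with the largest changes the 4 values on western diet lay outside the 4 on chow. Pck1 fell (-1.28 ± 0.23, adjusted p = 0.000319), as did Cyp2b10 (-1.41 ± 0.46, adjusted p = 0.0276), a drug-metabolising enzyme. Abcb11 (-0.21 ± 0.15, adjusted p = 0.329), Fgf21 (0.12 ± 0.34, adjusted p = 0.828) and Fasn (-0.011 ± 0.18, adjusted p = 0.973) did not pass.

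The diet changed 2693 of 9095 genes in wild type, 1407 up and 1286 down. With median scaling, which raised the median of all genes to 0.14, the split was 2082 up and 290 down. More than 2-fold changes numbered 355 up and 93 down, the unadjusted p was below 0.05 in 3649, and the groups did not overlap in 2639 (chance share 2.86%). On leaving out 1 array some calls were lost in at least 1 of 16 fits. Cyp2b10 (4 fits, adjusted p = 0.111) was weakest without wild type western replicate 2. Cth (5 fits, adjusted p = 0.0685) was weakest without wild type western replicate 3. Cdk1 (adjusted p = 0.0519) and Cyp2b10 (adjusted p = 0.104) were lost with the authors' values. Cth (adjusted p = 0.101) and Shmt1 (adjusted p = 0.0715) were lost with median scaling.

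In knockout mice, the comparison of western diet with chow asked which diet responses occur without SHP. The lipid synthesis genes Scd1 and Srebf1 rose 3.27-fold (1.71 ± 0.14, adjusted p = 8.17e-07) and 2.73-fold (1.45 ± 0.29, adjusted p = 0.00541), and Pparg rose 2.82-fold (1.5 ± 0.19, adjusted p = 0.000194). The cholesterol synthesis enzymes Sqle and Cyp51 fell 5.23-fold (-2.39 ± 0.26) and 2.97-fold (-1.57 ± 0.23). The largest rises were in Car3, a carbonic anhydrase, at 5.82-fold (2.54 ± 0.39), Hamp2, related to the iron hormone hepcidin (2.15 ± 0.48), Lgals1 (2.03 ± 0.21), a galectin, and Apoa4 (2.0 ± 0.37), an apolipoprotein. Cyp7a1 (1.09 ± 0.39, adjusted p = 0.0890), Cyp8b1 (-0.20 ± 0.24, adjusted p = 0.662), Cidec (0.34 ± 0.35, adjusted p = 0.610) and Col1a1 (0.27 ± 0.19, adjusted p = 0.425) did not pass.

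Cholesterol synthesis genes fell: 7 of 18 members fell (1 up and 10 down adjusted over the list alone, camera adjusted p = 7.74e-06, 0.666 with an estimated correlation). Tm7sf2 (-1.11 ± 0.17) and Idi1 (-0.79 ± 0.19) fell beside Sqle and Cyp51. Of fatty acid and triglyceride synthesis genes, 3 of 22 measured rose (9 up and 2 down adjusted over the list alone, camera adjusted p = 0.00206, 0.666 with an estimated correlation). The third was the desaturase Fads2 (0.76 ± 0.13). Fatty acid oxidation and PPARalpha targets moved the other way: 4 of 22 members fell (6 adjusted over the list alone, camera adjusted p = 0.00219, 0.666 with an estimated correlation). These were Cyp4a14 (-1.62 ± 0.43) and Cyp4a31 (-1.34 ± 0.32), which hydroxylate fatty acids, the peroxisomal enzyme Ehhadh (-1.16 ± 0.35) and the lipase inhibitor Angptl4 (-0.75 ± 0.19). In this list the score of knockout western replicate 3 lay below the other 3, and without this array the median of -0.25 was -0.15 (camera adjusted p = 0.0298). Without knockout western replicate 3 the change was -0.89 for Cyp4a14 and -0.87 for Cyp4a31. The 4 PPARalpha targets that fell became 1 without knockout chow replicate 1 or 2, 2 without knockout chow replicate 4 or knockout western replicate 3 and 2 with median scaling. The 7 cholesterol synthesis genes that fell became 4 without knockout chow replicate 1 or knockout western replicate 4 and 4 with median scaling. The 3 lipid synthesis genes that rose became 7 without knockout western replicate 1 and 5 with median scaling. Of oxidative phosphorylation genes, 5 of 28 measured rose and 2 fell (11 up and 3 down adjusted over the list alone, camera adjusted p = 0.00526, 0.666 with an estimated correlation). The largest changes were in Cox7a2 (0.67 ± 0.10), Uqcrb (0.57 ± 0.10), Ndufb5 (0.54 ± 0.12) and Ndufs4 (0.41 ± 0.086). The 2 members that fell became 1 without knockout chow replicate 2 or 3 or knockout western replicate 2, and 0 with median scaling.

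Of the macrophage and Kupffer cell markers, 5 of 22 members rose (8 adjusted over the list alone, camera adjusted p = 0.000214, 0.666 with an estimated correlation). They included H2-Aa (1.36 ± 0.34), Gpnmb (1.35 ± 0.37), Ctss (0.86 ± 0.21) and Lgals3 (0.80 ± 0.24). The diet response of Gpnmb and Lgals3 was smaller than in wild type by the interaction test (adjusted p = 0.000168 and adjusted p = 0.000682), while for H2-Aa (adjusted p = 0.372) and Ctss (adjusted p = 0.0612) no difference passed. Of drug-metabolising enzymes, 3 of 25 measured rose and 2 fell (5 up and 2 down adjusted over the list alone, camera adjusted p = 0.0315, 0.720 with an estimated correlation). Sult1e1, an estrogen sulfotransferase (at least 2.02-fold, 1.40 ± 0.18), and Gsta1 (at least 1.75-fold, 1.19 ± 0.36) rose from background, Fmo5 (0.52 ± 0.16) rose, and Cyp1a2 (-0.96 ± 0.22) fell. Drug-metabolising enzymes were not called without knockout chow replicate 2 (adjusted p = 0.110) or without knockout western replicate 2 (adjusted p = 0.320). The 3 drug-metabolising enzymes that rose became 1 without wild type chow replicate 2, 3 or 4, knockout chow replicate 2 or 4 or knockout western replicate 2 or 3 and 1 with the authors' values. The 2 enzymes that fell became 1 without wild type chow replicate 1 or 2, knockout chow replicate 1, 2 or 3, wild type western replicate 1, 3 or 4 or knockout western replicate 1, 3 or 4, and 1 with median scaling. The 5 macrophage markers that rose became 1 without knockout chow replicate 3 or knockout western replicate 4, 2 without knockout chow replicate 1 or 2 or knockout western replicate 1 or 2, 3 without background correction and 3 with normexp. Blood cell markers rose: 2 of 5 members rose (4 adjusted over the list alone, camera adjusted p = 0.000972, 0.666 with an estimated correlation). These were the erythroid genes Alas2 (0.52 ± 0.10) and Slc4a1 (0.58 ± 0.17). Without knockout western replicate 1 the change was 0.38 for Slc4a1. The 2 blood cell markers that rose became 1 without knockout chow replicate 1, 2 or 3 or knockout western replicate 1 or 4, 4 without knockout western replicate 3, 1 without background correction, 1 with normexp, 1 with median scaling and 1 with the authors' values.

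Further rises were in Inmt (1.84 ± 0.28), Cyp2c70, which makes muricholic acids (1.74 ± 0.28), and Aatk (1.73 ± 0.32). Further falls were in the chemokine Cxcl13 (-2.21 ± 0.53), the stress gene Gadd45b (-2.17 ± 0.30), the prostaglandin carrier Slco2a1 (-1.57 ± 0.12) and Tuba8, which was at background on western diet (at least 2.02-fold lower, -1.31 ± 0.21). The highest adjusted p of these was 0.0170, for Cxcl13. Abcb11 (-0.034 ± 0.15), Fasn (-0.091 ± 0.18), Pck1 (-0.28 ± 0.23), Fgf21 (-0.51 ± 0.34) and Cyp2b10 (-0.0019 ± 0.46) did not pass.

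Of 9095 genes, 717 passed, 411 up and 306 down, and 347 with median scaling (297 up and 50 down). More than 2-fold changes numbered 55 up and 23 down, the unadjusted p was below 0.05 in 2188, and the groups did not overlap in 1307 (chance share 2.86%). The count was 359 without knockout chow replicate 2 and 476 without knockout western replicate 4. On leaving out 1 array some calls were lost in at least 1 of 16 fits. Gpnmb (7 fits, adjusted p = 0.0902) and Lgals3 (9 fits, adjusted p = 0.124) were weakest without knockout western replicate 1. Ehhadh (11 fits, adjusted p = 0.160), Fmo5 (12 fits, adjusted p = 0.133), Slc4a1 (6 fits, adjusted p = 0.103), Cyp4a14 (3 fits, adjusted p = 0.0732) and Angptl4 (2 fits, adjusted p = 0.0637) were weakest without knockout chow replicate 2. Gsta1 (11 fits, adjusted p = 0.133) was weakest without knockout western replicate 2. Idi1 (3 fits, adjusted p = 0.0570), H2-Aa (2 fits, adjusted p = 0.0682) and Ctss (2 fits, adjusted p = 0.0570) were weakest without knockout western replicate 4. Cyp4a31 (1 fit, adjusted p = 0.0533) and Cxcl13 (1 fit, adjusted p = 0.0533) were weakest without knockout chow replicate 1. In turn Cyp7a1 passed without knockout chow replicate 3 (adjusted p = 0.0357). Cxcl13 (adjusted p = 0.0578) and Hsd3b5 (adjusted p = 0.124) were lost with the authors' values. Angptl4 (adjusted p = 0.103) was lost with median scaling. Ehhadh (adjusted p up to 0.0731) was lost with median scaling and without a detection filter. Gpnmb (adjusted p up to 0.202) was lost under both background alternatives. Fmo5 (adjusted p up to 0.0770) was lost with median scaling, with the authors' values and without a detection filter. Gsta1 (adjusted p up to 0.101) was lost under both background alternatives, with the authors' values and without a detection filter. Slc4a1 (adjusted p up to 0.0862) was lost under both background alternatives, with median scaling, with the authors' values and without a detection filter. Lgals3 (adjusted p up to 0.0689) was lost under both background alternatives, with median scaling, without a detection filter and with the replicate block.

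The interaction test asked whether the diet effect differed between genotypes. It passed for 641 of 9095 genes, of which 567 changed more with diet in wild type than in knockout. The genes with the smallest p all rose less in the knockout: the scaffold protein Sdcbp2 (-3.39 ± 0.22, adjusted p = 2.89e-08), Fndc10 (-2.62 ± 0.20), the calcium-binding proteins S100a11 (-2.81 ± 0.23), Anxa2 (-2.66 ± 0.25) and Anxa5 (-1.69 ± 0.17). The others were the fatty acid carrier Fabp3 (-1.60 ± 0.15), the neurotrophin receptor Ntrk2 (-2.06 ± 0.20), Ifi27l2b (-1.43 ± 0.14), Uap1l1 (-2.34 ± 0.24) and Haus8 (-1.99 ± 0.21). The highest adjusted p of these was 8.71e-06, for Haus8. Hsd3b5 had the opposite sign (5.46, adjusted p = 0.000100), with a fall in wild type and a rise of 1.81 ± 0.48 in knockout (adjusted p = 0.0269, lost in 5 of 16 fits, with adjusted p = 0.0820 without knockout chow replicate 2), and Cyp8b1 also differed (1.14, adjusted p = 0.0472, lost in 13 of 16 fits without 1 array). The difference passed for Cidec (-2.76, adjusted p = 0.00213) and Col1a1 (-1.54, adjusted p = 0.00181). It did not pass for Cyp7a1 (-1.03, adjusted p = 0.290), Scd1 (-0.28, adjusted p = 0.451), Srebf1 (-0.34, adjusted p = 0.685), Pparg (0.33, adjusted p = 0.514) or Pck1 (1.01, adjusted p = 0.0662). Hr was raised in the knockout by more on chow than on western diet (-2.40, adjusted p = 0.000168).

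As a called list, macrophage and Kupffer cell markers had a smaller diet rise in the knockout, 12 negative of 22 (0 positive and 16 negative adjusted over the list alone, camera adjusted p = 2.37e-16, 0.124 with an estimated correlation). So did fibrosis and stellate cell markers, 10 negative of 24 (0 positive and 19 negative adjusted over the list alone, camera adjusted p = 3.36e-13, 0.124 with an estimated correlation). Inflammatory cytokines and signalling gave 10 negative of 21 (0 positive and 13 negative adjusted over the list alone, camera adjusted p = 4.98e-11, 0.124 with an estimated correlation). Lipid droplet and PPARgamma targets gave 3 negative of 16 (1 positive and 7 negative adjusted over the list alone, camera adjusted p = 0.0107, 0.364 with an estimated correlation). Proliferation genes gave 1 negative of 15 (1 positive and 6 negative adjusted over the list alone, camera adjusted p = 0.00611, 0.364 with an estimated correlation). Male-biased liver genes were positive, 8 positive of 18 (13 positive and 0 negative adjusted over the list alone, camera adjusted p = 1.62e-11, 0.124 with an estimated correlation). So were methionine and one-carbon metabolism genes, 1 negative and 2 positive of 17 (6 positive and 1 negative adjusted over the list alone, camera adjusted p = 0.0480, 0.364 with an estimated correlation). Methionine and one-carbon genes were not called without wild type chow replicate 2 or 3, knockout chow replicate 1 or 2, wild type western replicate 2 or 3 or knockout western replicate 2 or 3 (adjusted p = 0.0532 to 0.105). Members that passed as positive numbered 0 in 5 of the 16 fits, 1 in 10 and 2 in 1. The 3 lipid droplet genes that were negative became 5 without wild type western replicate 2 or knockout western replicate 2 and 6 with median scaling. The 1 negative proliferation gene became 2 without wild type western replicate 1 or knockout western replicate 3 or 4, 3 without wild type western replicate 4 and 5 with median scaling. The 8 male-biased genes that were positive became 5 without wild type chow replicate 1. With the authors' values 6 fibrosis and 5 inflammatory genes were negative.

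Of the 641 genes, 208 were positive and 433 negative, and 75 and 503 with median scaling, whose median over all genes was -0.11. The unadjusted p was below 0.05 in 1961. For diet, 516 of the 641 passed in wild type alone, 51 in knockout alone and 53 in both. In 432 a positive wild type estimate was lower in knockout. With the authors' values Ntrk2 (adjusted p = 0.338), Ifi27l2b (0.0604), Gpnmb (0.0705), Cidea (0.309) and Col1a1 (0.197) did not pass. Array medians there were 7.6 to 7.7 and the lowest value -16.7, so the scale of low values may underlie such losses.

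**Figure D3:**
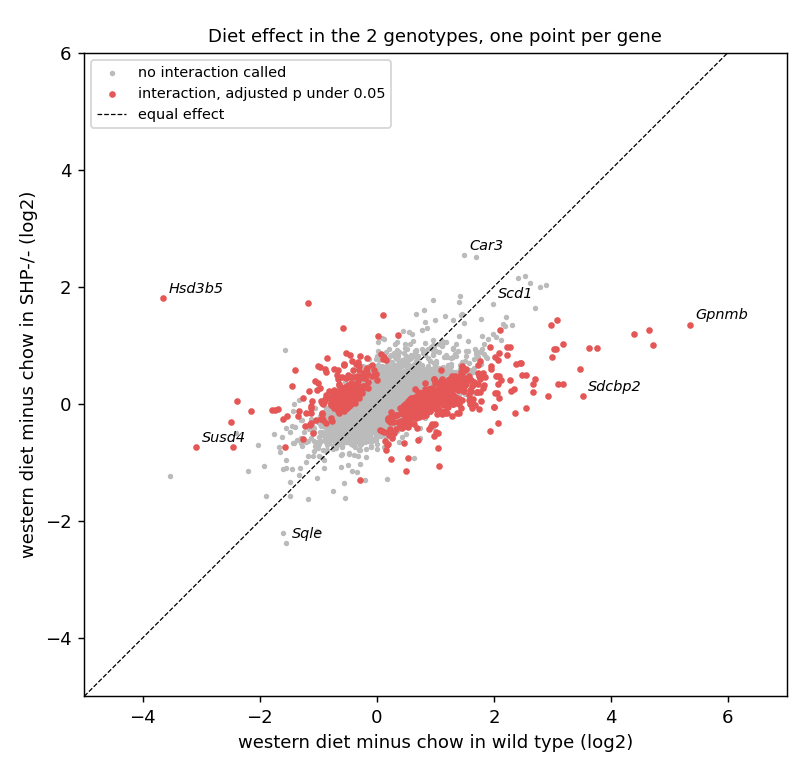
Log2 change with western diet in wild type (x axis) against that in knockout (y axis), 1 point per gene for 9095 genes, with genes that passed the interaction test in red. Across genes r was 0.526, and most red genes lie nearer to 0 on the y axis than on the x axis.

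Set against each other, the diet effects in wild type and knockout correlated across genes with r = 0.526 ± 0.0620 (jackknife SE over arrays) and rho = 0.472, and share no arrays. Both rose in 229 genes where independence gives 63.6, both fell in 170 (43.3), and 13 were called in opposite directions. The genotype effects on chow and on western diet gave r = 0.287 ± 0.0775 and rho = 0.168. Both rose in 25 genes (3.53 under independence), among them Asns, Cav1, Cyp7a1 and Csad, and both fell in 27 (3.95), among them Serpina12 and Pparg, with 3 opposite. Of these, 2 and 10 lie among the 100 genes nearest to Nr0b2. Of the 76 genes called on chow, 67 had the same sign on western diet. Genes are not independent replicates, so no p is given.

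**Figure D4:**
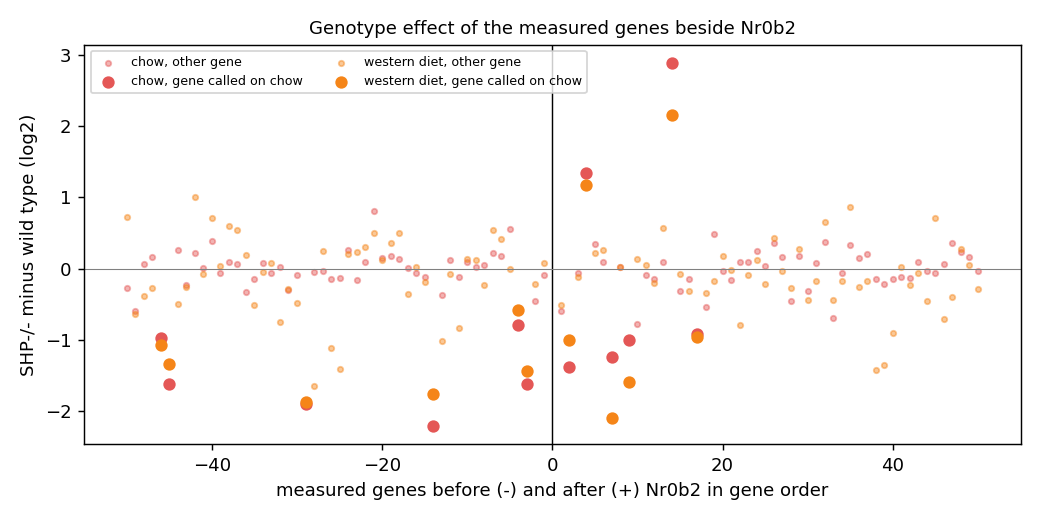
Log2 difference between knockout and wild type on chow and on western diet for the 50 measured genes on each side of Nr0b2, in gene order, with 1 point per gene. The 12 genes that passed on chow had the same sign on both diets.

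Of the 30 gene lists, 14 were called in no comparison. Their lowest camera adjusted p over the 5 comparisons was 0.178 for ER stress, 0.0959 for acute phase, 0.180 for adipocyte markers, 0.350 for bile acid and canalicular transport, 0.133 for bile acid synthesis, 0.308 for cholangiocyte markers, 0.135 for circadian clock and 0.268 for endothelial cell markers. It was 0.0822 for female-biased liver genes, 0.0989 for glucose metabolism, 0.263 for lipoproteins, 0.138 for neutrophil markers, 0.322 for oxidative stress and 0.127 for pancreas markers. No list was called in any comparison when camera estimated the correlation between members. The lowest adjusted p was then 0.0680, and lists with unadjusted p below 0.05 numbered 2, 6, 6, 1 and 4 in the order given. Fry, which asks whether a list moves one way without comparing it with other genes, called 1, 12, 19, 1 and 6. On simulated data with changes of 0.5, 1 and 2 on the log2 scale, the fit recovered 50.8%, 97.0% and 100% of the changed genes for the genotype on chow and 44.8%, 98.5% and 100% on western diet. It recovered 47.8%, 95.5% and 100% for diet in wild type, 58.2%, 95.5% and 98.5% in knockout and 19.4%, 79.1% and 100% for the interaction. All 5 shifted and 0 of 25 other lists were called, but independent genes leave list correlation untested. Unchanged genes called were 17, 4, 8, 7 and 7 in that order (9.34%, 2.41%, 4.71%, 4.00% and 5.04% of calls). Chow and interaction exceeded 5%, but each share here is from only 1 draw.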

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

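The test for strain variants near Nr0b2, the test of probe sequence there, the counts without the neighbours of Nr0b2, the refits of lists without single arrays and the other settings of the interaction genes were chosen after the result was seen, and the other tests in this part were planned. In the paragraphs on single arrays the value beside each item is the gap between the array farthest out and the nearest of the other 3 arrays of its group, divided by the range of the group. Items with a ratio above Dixon's limit for 4 samples are given. Chance alone passes this limit in about 5% of groups, and here 53 of 732 sets of 4 passed.

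Wild type chow replicate 1 lay above the others of its group for Dmgdh (0.924) and below them for Lpin1 (0.888). Wild type chow replicate 3 lay above the others of its group for Ccl4 (0.923), Mmp12 (0.859) and Tuba8 (0.908) and below them for Hpd (0.848). Wild type chow replicate 4 lay above the others of its group for Abcg5 (0.832) and below them for Apoc2 (0.854), Cidec (0.911), Cth (0.864), Slco2a1 (0.838) and the score of lipid droplet and PPARgamma targets (0.848).

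Knockout chow replicate 1 lay above the others of its group for Anxa5 (0.983) and Ly6d (0.937) and below them for Plin4 (0.969). Knockout chow replicate 2 lay above the others of its group for Cidea (0.835) and Cyp1a2 (0.931) and below them for Col1a1 (0.841) and Dmgdh (0.890). Knockout chow replicate 3 lay above the others of its group for Chac1 (0.842), Dbp (0.845) and the score of circadian clock (0.891) and below them for Elovl3 (0.867). Knockout chow replicate 4 lay above the others of its group for Mmp12 (0.844), Mmp13 (0.869), the score of blood cell markers (0.969) and the number of detected probes (0.855).

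Wild type western replicate 2 lay above the others of its group for Psat1 (0.847), Top2a (0.863) and the number of detected probes (0.837) and below them for Apoa4 (0.966), Cidec (0.857) and Ndufb5 (0.894). Wild type western replicate 3 lay above the others of its group for Fdps (0.885) and Fmo5 (0.915). Wild type western replicate 4 lay above the others of its group for Akr1c6 (0.893), Alas2 (0.860), Hpd (0.967) and Nudt7 (0.891) and below them for Slc39a4 (0.882).

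Knockout western replicate 1 lay above the others of its group for Col6a1 (0.874) and below them for Uqcrb (0.920). Knockout western replicate 3 lay above the others of its group for Cyp2c70 (0.846), Lcn2 (0.857) and Stard4 (0.852) and below them for Cbs (0.948), Cidec (0.842), Cyp4a14 (0.894), Srxn1 (0.905), the score of cholangiocyte markers (0.858) and the score of fatty acid oxidation and PPARalpha targets (0.888). Knockout western replicate 4 lay above the others of its group for Mcm5 (0.933) and Serpinc1 (0.858). Knockout western replicate 3 gave 9 of the 53, the most of any array.

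The diet effect differed between the genotypes for 55 named genes and 7 lists, by the interaction test (n = 4 per group). The values are the log2 diet effect in knockout minus that in wild type. It was negative for 41 genes: Gpnmb (-4.01), Cidea (-3.71), Ly6d (-3.40), Sdcbp2 (-3.39), Gsta1 (-3.20), Mmp12 (-2.89), Lpl (-2.84), S100a11 (-2.81), Trem2 (-2.78), Cidec (-2.76), Anxa2 (-2.66), Fndc10 (-2.62), Hr (-2.40), Uap1l1 (-2.34), Lgals3 (-2.20), Lcn2 (-2.16), Ccl4 (-2.09), Atf3 (-2.06), Ntrk2 (-2.06), Haus8 (-1.99), Col3a1 (-1.77), Tlr2 (-1.71), Lyve1 (-1.69), Anxa5 (-1.69), Cyp17a1 (-1.65), Timp1 (-1.61), Fabp3 (-1.60), Gsta2 (-1.56), Col1a1 (-1.54), Ifi27l2b (-1.43), Psat1 (-1.33), Srxn1 (-1.31), Tnfaip3 (-1.27), Mcm6 (-1.26), Gldn (-1.19), Cxcl10 (-1.13), Tuba8 (-1.03), Pf4 (-0.94), Nfe2l2 (-0.91), Pltp (-0.88) and Abcg5 (-0.82). It was positive for 14 genes: Hsd3b5 (5.46), Aatk (2.90), Cyp7b1 (2.44), Susd4 (2.35), Elovl3 (2.17), Obp2a (2.03), Avpr1a (1.72), Dct (1.63), Nudt7 (1.41), Cyp8b1 (1.14), Nr1i3 (1.06), Ppp1r3b (1.01), Hpd (0.95) and Alas2 (0.69). The highest adjusted p among the 55 genes was 0.0472, for Cyp8b1. Of the 55 genes 36 passed in every other setting run. Among the 16 fits without 1 array 9 genes were lost in some, given with the highest adjusted p. These were Cyp8b1 (13 fits, 0.0991), Pf4 (11 fits, 0.0893), Tuba8 (11 fits, 0.0911) and Gldn (3 fits, 0.0613) without wild type western replicate 2, Nfe2l2 (11 fits, 0.0695) and Cxcl10 (10 fits, 0.0776) without wild type chow replicate 4. The others were Ppp1r3b (9 fits, 0.0819) without knockout chow replicate 4 and Elovl3 (7 fits, 0.0675) and Gsta2 (1 fit, 0.0511) without wild type chow replicate 1. Atf3, Ccl4, Cidea, Col1a1, Gldn, Gpnmb, Gsta1, Gsta2, Ifi27l2b, Ntrk2, Psat1 and Timp1 were lost with the authors' values (adjusted p up to 0.338). Without a detection filter others were lost too, given with the highest adjusted p of these settings. These were Cxcl10 and Cyp8b1 (also authors' values, 0.362), Nfe2l2 (also authors' values and replicate block, 0.0606) and Ppp1r3b (also median scaling and authors' values, 0.0986). Pf4 (also authors' values, 0.491) and Tuba8 (also replicate block, 0.0855) were lost under both background alternatives as well. As the median over members, it was -0.87 for fibrosis and stellate cell markers, -0.94 for inflammatory cytokines and signalling, -0.47 for lipid droplet and PPARgamma targets, -1.06 for macrophage and Kupffer cell markers, 1.14 for male-biased liver genes, 0.33 for methionine and one-carbon metabolism and -0.44 for proliferation. For these lists the call did not hold with an estimated correlation, where the lowest adjusted p was 0.124. The median of methionine and one-carbon metabolism was 0.20 without knockout chow replicate 2, and its call was lost in 8 of 16 fits that leave out 1 array. Without background correction, with normexp and with the authors' values the medians were -0.55, -0.52 and -1.62 for inflammatory cytokines and signalling and -0.25, -0.24 and -1.33 for proliferation.

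Macrophage and Kupffer cell markers rose with western diet in wild type, by 1.87 as a mean log2 score, and their diet effect was smaller in the knockout. A lower share of hepatocytes would raise the markers of other cell types alike. Endothelial markers rose by 0.15 (difference 1.71, exact permutation p = 0.0286, the smallest for 4 against 4 arrays) but fibrosis markers by 1.00. Cell share stays open in part. Brighter arrays or scaling would leave less under other processing, but the lowest median of 4 other settings was 80.4% of the reported one. More macrophages, or a change in what they express, may underlie the rise as a hypothesis of a diet response that depends on SHP, and these data do not separate the 2. Slides were not given and stay untested.

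Male-biased liver genes fell with western diet in wild type, by a mean score of -1.28, and the interaction was positive. A lower share of hepatocytes would lower every hepatocyte gene alike, but hepatocyte markers moved by -0.26, a difference of -1.02 (exact permutation p = 0.0286). The scaling of this group does not account for it either, since the lowest median under 4 other settings was 89.2% of the reported one. A change of hepatocyte state by diet and genotype, such as in the hormone signals that set the male pattern, may underlie it as a hypothesis. Hormones were not measured, and slides stay untested.

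Genes changed in knockout on chow gathered near Nr0b2 on its chromosome: 12 of the 100 nearest measured genes passed against 0.712% of the others (Fisher's exact test, p = 2.76e-11, odds ratio 19). They were Zbtb8os, Bsdc1, Serinc2, Xkr8, Map3k6, Sytl1, Gpn2, Cd52, Sh3bgrl3 and Paqr7, which fell, and Hmgn2 and Extl1, which rose. All 12 passed with the same sign on western diet and 0 had an interaction, against 40 and 16 of the other 64 genes called on chow. Variants of the donor strain carried along with the targeted locus may account for these 12, which would then not be effects of losing SHP, and regulation by a neighbouring deletion stays open as well. For the 10 that fell, a sequence difference under the probe cannot be told from lower expression, since probe sequences were not analysed.

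Every split of the 8 arrays of a comparison into 4 and 4 was fitted in the same way. The real split had the most genes of 35 splits in all 4 comparisons of 2 groups, but 1 in 35 does not exclude chance. On chow it gave 76 genes and the highest other split 2, on western diet 1799 and 2, for the diet in wild type 2693 and 0, and for the diet in knockout 717 and 6. For the interaction 4 of 100 regroupings of the genotype labels within diets gave 641 genes or more, the real one included. The 3 others as large kept the genotypes apart on western diet and gave 731 to 991 genes, which points to that genotype difference. The other 96 gave at most 2, but they mix the genotypes on western diet and so remove that difference itself. The regroupings therefore do not decide whether chance gives the interaction count.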

How the results depend on the processing

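The counts without the neighbours of Nr0b2, the list counts on leaving out 1 array and the fits without an array outside the comparison were chosen after seeing the data. Of 220 calls of named genes, 177 held in every alternative run for single genes. On leaving out 1 array 34 were lost in at least 1 fit, and under other settings 31, which makes 43 in all. Of 25 named values that did not pass, 2 passed in some setting (Cyp2b10 on chow and Cyp7a1 for the diet in knockout), and 0 changed direction past the threshold. With all arrays in the fit, the counts of changed genes stayed within 1.5 times the reported one except for 124 on chow with array weights, against 76, and 347 for the diet in knockout with median scaling, against 717, where the cause was not tested. On leaving out 1 array the counts ran from 49 (without wild type chow replicate 3) to 108 (without knockout western replicate 3) on chow, 1336 to 1796 on western diet, 2241 to 2772 for the diet in wild type, 359 (without knockout chow replicate 2) to 742 for the diet in knockout, where they were 476 without knockout western replicate 4, and 458 to 714 for the interaction. Fewer arrays leave fewer degrees of freedom. The correlations across genes ran from 0.226 to 0.322 for the genotype effects and from 0.491 to 0.545 for the diet effects, whose r was 0.422 with the authors' values, the cause of which was not tested.

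Median scaling put the median log2 change of all genes at -0.062, -0.16, 0.14, 0.054 and -0.11 in the order chow, western diet, diet in wild type, diet in knockout and interaction. The splits into up and down were then 21 and 39, 208 and 1691, 2082 and 290, 297 and 50, and 75 and 503, so the balance of directions rests on the scaling, while the lists called rose to 13 on western diet and 12 for the interaction. With an estimated correlation 0 lists were called in any comparison. With fry 1 list was called on chow, 19 for the diet in wild type and 1 for the diet in knockout. With single arrays left out the lists called ran from 2 (in 3 fits) to 5 (without wild type chow replicate 1) on chow, against 3, and from 8 to 9 on western diet. They ran from 10 to 13 for the diet in wild type, 6 to 9 for the diet in knockout and 6 to 10 for the interaction. With the replicate block the counts were 70, 1738, 2672, 682 and 614. Arrays with the same replicate number did not pair: the mean r of their residuals was 0.011 over 24 pairs (-0.17 to 0.19) and -0.0037 over 72 pairs of different numbers, and 6 of 16 arrays had their best partner in their own number. Without the neighbours of Nr0b2, 59 and 1749 genes passed on chow and on western diet. Slide as a block was not run, since slides are not given, and Nr0b2 gives no value in any setting. Signal over background limits genes such as Gpnmb and Hsd3b5, which were detected in only part of the arrays of 1 group, and folds against such a level are compressed by the offset.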

Other observations

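The tests of the clock genes in this part were chosen after the result was seen, as were the look at knockout western replicate 3 and the fits without an array outside a comparison. Several genes of lists that were not called also changed with western diet in wild type livers (n = 4 per group). The sterol exporter pair Abcg5 (1.29 ± 0.12) and Abcg8 (0.61 ± 0.12) rose, as did the apolipoprotein Apoa4 (2.79 ± 0.37) and the phospholipid transfer protein Pltp (1.28 ± 0.14). Acute phase genes rose in 6 of 19 members and fell in 2 (6 and 2 adjusted over the list alone, camera adjusted p = 0.0959), led by Lcn2 (3.18 ± 0.35) and Orm2 (1.89 ± 0.32). The neutrophil calprotectin genes S100a8 (1.46 ± 0.37) and S100a9 (1.11 ± 0.38) rose, with 2 of 6 markers passing (2 adjusted over the list alone, camera adjusted p = 0.138), and so did the platelet factor Pf4 from background (at least 2.10-fold, 1.28 ± 0.19). Of glucose metabolism genes 2 of 17 rose and 6 fell (2 and 6 adjusted over the list alone, camera adjusted p = 0.0989), the largest fall being in G6pc (-1.55 ± 0.18), the glucose-6-phosphatase. Stress genes went both ways: 3 of 17 ER stress genes rose and 5 fell (3 and 6 adjusted over the list alone, camera adjusted p = 0.639), with Atf3 (2.0 ± 0.20) and Chac1 (1.46 ± 0.23) up, and 4 of 14 oxidative stress genes rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.322), with Nfe2l2 (1.17 ± 0.18) up and the metallothionein Mt2 (-1.13 ± 0.37) down. Gsta2 (2.03 ± 0.28) and Ntrk2 (2.55 ± 0.14) rose, and the fatty acid hydroxylases Cyp4a31 (-1.48 ± 0.32) and Cyp4a14 (-1.18 ± 0.43) fell. Endothelial markers went both ways, with Lyve1 (1.62 ± 0.20) up and Ehd3 (-0.96 ± 0.12) down, as did clock genes, with Dbp (2.53 ± 0.80) up and Nfil3 (-1.45 ± 0.28) down. Cholangiocyte markers Bicc1 (1.06 ± 0.21) and Tspan8 (at least 1.32-fold, 0.74 ± 0.21) and the adipocyte gene Car3 (1.49 ± 0.39) rose. Members that rose and fell (in parentheses those adjusted over the list alone) numbered 3 and 3 of 13 for bile acid and canalicular transport (4 and 4, camera adjusted p = 0.449), 3 and 3 of 17 for lipoproteins (3 and 3, camera adjusted p = 0.939) and 2 and 1 of 8 for female-biased liver genes (2 and 1, camera adjusted p = 0.0822). They numbered 3 and 3 of 17 for endothelial cell markers (3 and 3, camera adjusted p = 0.268), 2 and 2 of 15 for circadian clock (2 and 2, camera adjusted p = 0.947) and 2 and 0 of 7 for cholangiocyte markers (2 and 0, camera adjusted p = 0.308). The numbers were 2 and 0 of 4 for adipocyte markers (2 and 0, camera adjusted p = 0.193), 1 and 0 of 5 for blood cell markers (1 and 0, camera adjusted p = 0.193) and 1 and 7 of 22 for fatty acid oxidation and PPARalpha targets (1 and 7, camera adjusted p = 0.145). Further ones were 8 and 5 of 25 for drug-metabolising enzymes (8 and 6, camera adjusted p = 0.145). The highest adjusted p of these was 0.0479, for Cyp4a14. Some calls were lost in at least 1 of 16 fits without 1 array. Cyp4a14 (12 fits, adjusted p = 0.122) and Tspan8 (1 fit, adjusted p = 0.0524) were weakest without wild type western replicate 3. S100a9 (5 fits, adjusted p = 0.120) was weakest without wild type western replicate 2. Dbp (4 fits, adjusted p = 0.0779) was weakest without wild type chow replicate 4. Mt2 (4 fits, adjusted p = 0.0893) was weakest without wild type chow replicate 2. Without wild type western replicate 2 the change was 0.61 for S100a9. With median scaling Mt2 (adjusted p = 0.0974) did not pass, nor S100a9 without a detection filter (adjusted p = 0.0533), nor Cyp4a14 without one or with the authors' values (at most adjusted p = 0.0723).

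In knockout livers on western diet the acute phase genes Lcn2 (-2.26 ± 0.35) and Saa3 (-2.09 ± 0.41) were lower than in wild type, with 6 of 19 members down and 1 up (7 and 1 adjusted over the list alone, camera adjusted p = 0.187). So were the stress genes Atf3 (-1.98 ± 0.20), Nfe2l2 (-0.80 ± 0.18) and Srxn1 (-0.94 ± 0.18), the female-biased genes Ntrk2 (-2.35 ± 0.14) and Cyp17a1 (-1.52 ± 0.25), and Gsta2 (-2.63 ± 0.28) and Lyve1 (-1.13 ± 0.20). Higher were the xenobiotic receptor Nr1i3 (0.81 ± 0.19), the hepatocyte genes Hpd (0.67 ± 0.12) and Serpinc1 (0.62 ± 0.13), Ehd3 (0.50 ± 0.12) and the glycogen-targeting subunit Ppp1r3b (0.61 ± 0.20). Members that rose and fell (in parentheses those adjusted over the list alone) numbered 1 and 3 of 17 for ER stress (1 and 3, camera adjusted p = 0.373), 1 and 3 of 14 for oxidative stress (1 and 3, camera adjusted p = 0.347) and 1 and 2 of 8 for female-biased liver genes (1 and 2, camera adjusted p = 0.195). They numbered 2 and 3 of 17 for endothelial cell markers (3 and 3, camera adjusted p = 0.314), 2 and 0 of 17 for glucose metabolism (1 and 0, camera adjusted p = 0.347) and 5 and 7 of 25 for drug-metabolising enzymes (5 and 7, camera adjusted p = 0.472). The numbers were 2 and 1 of 21 for nuclear receptors and partners of the SHP pathway (2 and 1, camera adjusted p = 0.314) and 4 and 1 of 18 for hepatocyte markers (4 and 1, camera adjusted p = 0.0750). With median scaling Ehd3 (adjusted p = 0.395) and Serpinc1 (adjusted p = 0.0936) did not pass, Ppp1r3b was lost with it and without a detection filter (at most adjusted p = 0.277), and on leaving out 1 array in 3 of 16 fits (adjusted p = 0.152 without wild type western replicate 2). Without wild type western replicate 2 the change was 0.37 for Ppp1r3b. In knockout mice the diet raised Nudt7 (1.51 ± 0.24), a peroxisomal hydrolase, Col6a1 (0.90 ± 0.19), Akr1c6 (0.83 ± 0.19) and Apoc2 (0.59 ± 0.13). It lowered the growth factor binding protein Igfbp1 (-1.49 ± 0.35), the insulin receptor substrate Irs2 (-1.27 ± 0.27) and the matricellular Ccn2 (-1.31 ± 0.30). Members that rose and fell (in parentheses those adjusted over the list alone) numbered 2 and 3 of 17 for glucose metabolism (2 and 4, camera adjusted p = 0.503), 2 and 1 of 16 for bile acid synthesis (3 and 2, camera adjusted p = 0.742) and 2 and 1 of 17 for lipoproteins (3 and 2, camera adjusted p = 0.546). They numbered 3 and 1 of 18 for male-biased liver genes (4 and 2, camera adjusted p = 0.199) and 2 and 2 of 24 for fibrosis and stellate cell markers (2 and 2, camera adjusted p = 0.386). Of the 7 genes named, the diet effect differed from wild type by the interaction test for Nudt7 (1.41, adjusted p = 0.0176) alone. Ccn2 (adjusted p = 0.0516) and Igfbp1 (adjusted p = 0.0543) did not pass without knockout chow replicate 2.

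Knockout western replicate 3 carried the pancreas transcripts Cela3b and Clps at log2 levels of 6.86 and 6.71, and its score over 3 pancreas markers was 1.64. The score averaged 0.45 ± 0.81 in its group against -0.07 in wild type chow, -0.13 in knockout chow and -0.25 in wild type western (SD, n = 4). The score of fatty acid oxidation and PPARalpha targets in this array was -0.71, with -0.13 in the nearest array of its group.

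Clock genes varied between mice of one group, as in knockout chow replicate 3, and a candidate explanation is that mice of a group were killed at different points of the daily or feeding cycle. A clock score, the mean of 9 evening-phase genes minus that of 3 morning-phase genes, was set against 5 list scores over the 16 arrays, each as the deviation from its group mean, with permutation tests. With fatty acid and triglyceride synthesis genes r was 0.607 (permutation p = 0.00593, adjusted over the 5 relations 0.0297) and rho 0.591 (permutation p = 0.0334, adjusted 0.167), and r was 0.588 without the 2 arrays with the farthest clock scores. With fatty acid oxidation genes r was -0.456 (permutation p = 0.153, adjusted 0.382) and rho -0.212 (permutation p = 0.495, adjusted 0.619), and r was -0.327 without those 2 arrays. With cholesterol synthesis, ER stress and pancreas scores r was 0.137, 0.232 and 0.267 (permutation p = 0.678, 0.413 and 0.373, adjusted 0.678, 0.516 and 0.516), and rho 0.121, 0.256 and 0.200 (permutation p = 0.687, 0.386 and 0.472, adjusted 0.687, 0.619 and 0.619). Neither relation decides for or against the hypothesis, since for lipid synthesis rho missed the threshold after adjustment, for oxidation both coefficients missed it, and the times of death are not given.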
